A study of Mus musculus with 4 samples.

How the data were processed

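Whole-genome bisulfite sequencing was made from mouse embryonic stem cells of strain 129S6/SvEvTac kept in serum with leukemia inhibitory factor. SNF2H, encoded by Smarca5, is an ATPase that moves nucleosomes in ISWI remodelling complexes. The labels give 4 genotypes with 1 library each: wild type, Snf2h knockout, and knockout cells that express wild-type SNF2H again (wild-type add-back) or an ATPase mutant (mutant add-back). Per the labels' growth protocol, the knockout and the mutant add-back line passed through culture on fibroblast feeders after thawing, while the others grew on gelatin, so feeder culture follows the absence of working SNF2H. Per the labels' protocols, genomic DNA was sheared by sonication, ligated to adapters, treated with bisulfite and amplified by PCR. Bisulfite turns unmethylated cytosine into uracil, so a cytosine that still reads as cytosine is called methylated.

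The authors deposited counts: per CpG, the number of calls and how many of them were methylated. Each library lists the same 21908008 CpGs on build GRCm38. Per the submitters' processing notes, bcl2fastq 2.17 and cutadapt 1.15 were used. The aligner, the methylation caller and the handling of duplicate reads are not given in the sources used here. Calls on chromosomes 1 to 19 and X were used, which hold 21353092 of the CpGs.

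The libraries held 135792005, 142715940, 15196693 and 14489608 calls on chromosomes (wild type, knockout, wild-type add-back, mutant add-back). CpGs whose summed calls lay above the 99.9th percentile (over 87 calls, 20476 CpGs) were left out, because such depth points to collapsed repeats. They held 15.5, 20.9, 20.6 and 17.9% of the calls. The calls left gave a mean of 5.48, 5.38, 0.577 and 0.569 per autosomal CpG and covered 84.4, 82.8, 34.7 and 35.0% of the CpGs. The add-back libraries therefore give precise values for sets of regions and few for single regions.

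The design had set a minimum of 5 calls per CpG in every library. That leaves 37442 CpGs, so mean levels were taken over the 3781550 CpGs with at least 1 call in all 4 libraries, and the minimum of 5 became an alternative. Region tests used all calls of a region, with no minimum per CpG. These changes, the 10 kb and 100 kb windows and the coverage limit were made after the depth was seen. The tests, regions, gene lists and naming rule were otherwise fixed before the data were examined, with these exceptions. The design had set promoters around the gene start, which the CpG-richer gene end replaced because the gene table holds no strand. The minimum of 10 calls in the naming rule was not in the design.

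Low-methylated regions (LMRs) and unmethylated regions (UMRs) were runs of at least 4 CpGs with a level under 50% after smoothing over 3 CpGs in the summed calls of the 4 libraries, using CpGs with at least 5 summed calls. Runs of 30 or more CpGs were UMRs and shorter ones LMRs, which gave 6514 UMRs with a median of 41 CpGs and 91611 LMRs with a median of 6. Gene positions came from a RefSeq table of the same build, which holds no strand and no exons. A gene end window spans 1000 bp on each side of the CpG-richer end of a protein-coding gene, or of a noncoding gene on the lists below. Of 21469 windows, 21460 belong to protein-coding genes, and the counts of gene ends use those. Of these ends 24.7% overlap a UMR, against 4.37% of the other ends, and a window holds the promoter only where the CpG-richer end is the start of the gene. Neither strand nor exon or UTR could be given for a region.

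For LMRs, gene end windows (at least 5 CpGs), 1 kb tiles (at least 3 CpGs) and 10 kb windows, the methylated and unmethylated calls of each region were compared between libraries by a two-sided Fisher's exact test where both held at least 30 calls. A region gained or lost methylation at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 20 percentage points. With 1 library per genotype no difference has a replicate check. The test compares libraries, not genotypes, and CpGs on the same read are not independent, so its p-values are too small for a statement about genotypes. Intervals on levels of region sets are 95% bootstrap intervals over regions (1000 draws), and intervals on single regions are Wilson intervals. Both cover counting error or the choice of regions only, since PCR reads without molecular identifiers are not independent molecules.

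Of the comparisons made, knockout minus wild type and mutant minus wild-type add-back share no library. Wild-type add-back minus knockout, wild-type add-back minus wild type and mutant add-back minus knockout reuse the same libraries. Gene lists were fixed for imprinted, germline, pluripotency, early lineage, Hox, polycomb-bound developmental transcription factor, 2-cell stage, chromatin remodeller, DNA methylation, clustered protocadherin and fibroblast feeder genes. Of 366 listed genes 365 were found in the gene table. Each list's median difference was set among 10000 random lists of the same size matched on mean methylation and CpG number, as a description of these libraries. Genes named are the 10 largest gains and losses past the test with the same direction by at least 20 points, on at least 10 calls per library, in the other independent pair, filled up from that comparison alone where fewer qualified. All called list members, 5 LMRs each way, and the 5 largest gene ends each way in the other comparisons were added.

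The calling procedure was tested on simulated gains, with independent calls drawn at the real depths. In knockout minus wild type, shifts of 20, 30 and 40 points were given to 67, 67 and 66 of the 52893 LMRs, of which it recovered 7, 31 and 45, with 4 false losses. In the add-back pair, 64, 64 and 63 of 383 LMRs were shifted, of which it recovered 15, 49 and 58, with 1 false gain. Alternatives covered the coverage minimum, summed calls against mean CpG levels, the size of the difference, equal depth and centring on the median difference. They also covered region definitions, window width, the other gene end and the X chromosome. Centring shifted the difference of each region but left Fisher's exact test on the uncentred calls. Levels at CTCF, REST, OCT4-SOX2, NRF1 and YY1 motifs were planned but not analysed here, since they need the genome sequence, which was not used here. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.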

Results

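CpG methylation was measured across the genome of mouse embryonic stem cells in 4 libraries, 1 per genotype: wild type, Snf2h knockout, and knockout cells with wild-type or ATPase-mutant SNF2H added back. The question was how DNA methylation depends on SNF2H and on its ATPase. Wild type and knockout held 135792005 and 142715940 calls, the wild-type and mutant add-backs 15196693 and 14489608. There were no replicates, so differences are reported between libraries, with counting error or the spread over chromosomes or regions. Feeder culture after thawing went with the absence of working SNF2H.

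The targeted gene, Smarca5, spans 80699943 to 80739459 on chromosome 8 of GRCm38. Outside its CpG-rich end, the longest run of CpGs without a call in the knockout was 1 CpG, and the gene's coverage was 1.47 times the library mean, against 1.5 times in wild type. A deletion at the level of exons could not be examined with these gene positions, so coverage neither shows nor excludes the targeted change. In the mutant add-back, 15 CpGs between positions 80704732 and 80719683 carried 194 times the library's mean coverage, with 16 to 237 calls each, against 2.89 times in the wild-type add-back, 2.75 in the knockout and 2.88 in wild type. The other 344 CpGs of the gene had 1.81 times the library mean in the mutant add-back. Of the calls at the 15 CpGs, 72.9% were methylated in the mutant add-back. The CpG-rich end of Smarca5 gained methylation in the knockout, from 9.24% (Wilson interval 6.18 to 13.6%, 238 calls) to 30% (23.9 to 36.9%, 190 calls). It stood at 30% in the wild-type add-back (10 calls) and 17.6% in the mutant add-back (17 calls).

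**Figure D1:**
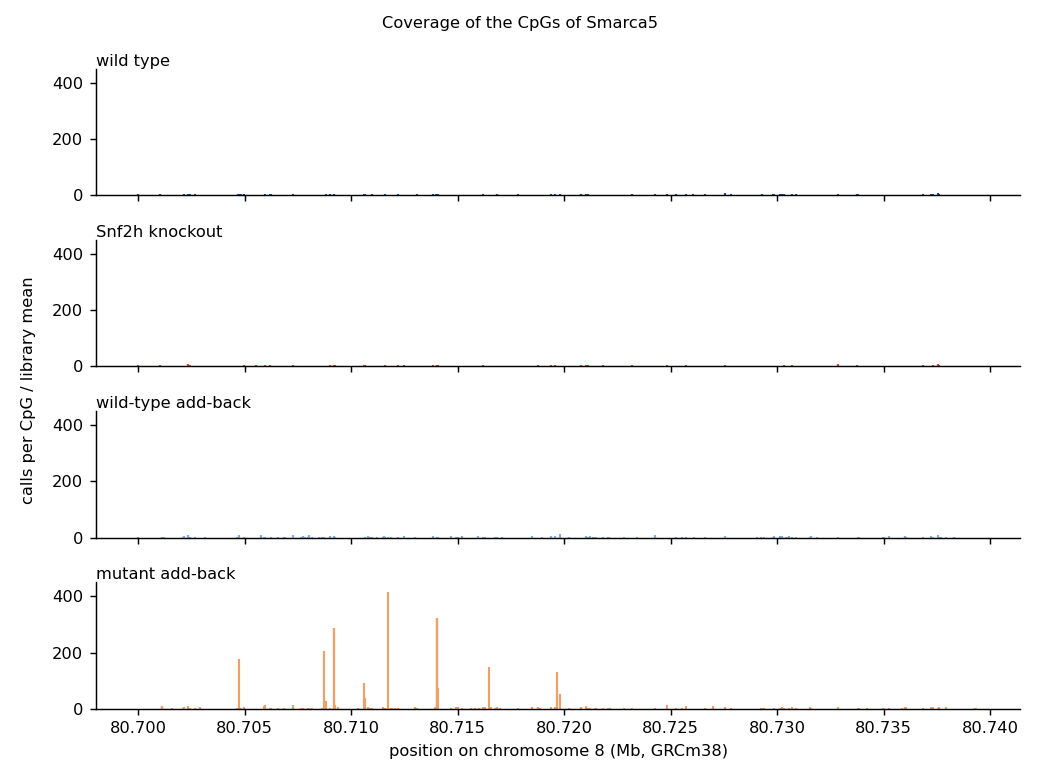
Coverage of each CpG across Smarca5 on chromosome 8 (position on the x axis, calls over the library mean on the y axis), 1 panel per library. In the mutant add-back, 15 CpGs reach a mean of 194 times the library mean, and the other CpGs average 1.81 times.

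Without SNF2H, methylation was lower nearly everywhere outside CpG-dense sequence. The mean CpG level was 73.0% in wild type and 64.3% in the knockout, a difference of -8.67 points over 3781550 CpGs. The difference was negative on 20 of 20 chromosomes, with an SD of 0.621 points over the 19 autosomes, and in 99.6% of 24938 windows of 100 kb. The X chromosome differed by -12.6 points, against a mean of -8.55 over the autosomes. Sequence between genes differed by -10.2 points and gene bodies by -7.29. At CpGs with 1 to 5 CpGs within 500 bp the difference was -11.9 points, while at those with over 40 it was 2.18. LMRs, the runs of fewer than 30 CpGs, stood at 34.4% in wild type and 27.1% in the knockout (difference -7.26 points, bootstrap interval -7.45 to -7.07). UMRs, the runs of 30 or more CpGs, stood at 14.9 and 14.5% (difference -0.332, interval -0.627 to -0.0300). The LMR and UMR differences depended on how regions were defined: under a level limit of 30% and at least 6 CpGs both turned positive, 1.31 and 1.26 points. With the planned minimum of 5 calls per CpG in all libraries, they were -12.1 and 1.44 points.

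Of 52893 LMRs tested, 7996 lost and 2257 gained methylation in the knockout. Their median wild-type levels were 53.5% at lost and 12.6% at gained LMRs, against 31.25% at the other tested ones. Regions were defined on summed calls, so a lost LMR need not have been low-methylated in wild type. Under the stricter region definition (30% and 6 CpGs) 531 of 16538 gained and 293 lost. Of 1348432 tiles of 1 kb, 103661 lost and 6153 gained, and of 251285 windows of 10 kb, 12132 lost and 64 gained. At gene ends the counts were closer, with 966 losses and 587 gains among 20051 (966 and 579 distinct windows). With 500 bp on each side in place of 1000, gains outnumbered losses, 692 against 565 of 15688. At the CpG-poorer gene end, 1145 of 18921 lost and 181 gained. At the depth of the shallowest library, 1668 of 185044 windows of 10 kb were lost and 24 gained, and 0 of 460 gene ends were lost and 10 gained. Centred on the median difference, 690 windows of 10 kb were lost and 331 gained, 5129 LMRs were lost and 2996 gained, and 55878 tiles of 1 kb were lost and 7610 gained. Only the difference was centred, while Fisher's exact test stayed on the uncentred calls. A centred gain had a smaller uncentred difference than a centred loss and passed that test less easily, so these counts do not weigh both directions alike.

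Among named LMRs, the largest losses shared by both independent pairs lay inside Bmp6, a bone morphogenetic protein gene, and 4929 bp from Klf4, which encodes a pluripotency transcription factor. The Bmp6 region (chromosome 13, 38353295 to 38354027) stood at 64.8% in wild type (Wilson interval 51.5 to 76.2%, 54 calls) and 5.19% in the knockout (2.04 to 12.6%, 77 calls), with 60.9% and 20% in the wild-type and mutant add-backs. The Klf4 region (chromosome 4, 55521815 to 55522208) stood at 57.1 and 4.17%, with 70% and 10% on 10 calls each in the add-backs. A region 1399 bp from Tfap2a, a transcription factor gene, stood at 59.1 and 11.8%, and 33.3 and 3.70% in the add-backs. Regions nearest to Edil3 and Cdh11, 368633 and 581760 bp away, were the others. The shared gains included a pair of regions nearest to Trim27, which encodes a RING finger ubiquitin ligase. At 21215352 to 21216156 on chromosome 13 the level was 2.05% in wild type (0.801 to 5.15%, 195 calls) and 74.0% in the knockout (67.4 to 79.6%, 196 calls), and 7.69 and 54.5% in the add-backs. At 21222091 to 21222987 it was 2.11 and 69.4%, then 9.52 and 81.8%. The remaining gains lay 2450 bp from Abt1 (9.80 to 71.3%), inside Reg4 (9.71 to 73.5%) and 44018 bp from Gm41408 (8.82 to 85%).

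Gene ends that gained in the knockout and were at least 20 points higher in the mutant than in the wild-type add-back included those of Cgrrf1, a cell growth regulator, Dhx34, an RNA helicase of nonsense-mediated decay, Nefm, a neurofilament subunit, and Ska1, a spindle and kinetochore protein. The end of Cgrrf1 went from 11.6% (Wilson interval 8.39 to 15.9%, 284 calls) to 77.1% (72.7 to 81.0%, 393 calls; adjusted p = 1.45e-65, Fisher's exact test), with 29.2 and 93.8% in the add-backs. Dhx34 went from 11.5 to 69.5%, with 18.8 and 75% in the add-backs. Nefm went from 4.85 to 56.5%, and Ska1 from 16.5 to 62.1%, with 16.7 and 83.3% in the add-backs. Hydin, needed for motile cilia, went from 23.8 to 67.2%, Gimap9 from 17.7 to 66.9% and Tnfrsf22 from 13.6 to 62.8%. Aipl1 and Pimreg share a window that went from 22 to 66.5%. Gene ends that lost by the same rule included Gipc1, a PDZ adaptor (76.4 to 27.3%, and 90.9 against 18.2% in the add-backs) and Tnni3, cardiac troponin I (68.6 to 30.6%, and 90 against 30%). Pla2g12b (77.6 to 28.9%), Spdef (77.0 to 37.2%), Cdh19 (72.9 to 34.7%), Nup160 (79.2 to 42.4%), Slc4a9 (75 to 39.8%) and the olfactory receptor genes Olfr1140 (57.4 to 17.6%) and Olfr1034 (67.2 to 28.8%) did too. Each add-back value here rests on 10 to 36 calls except at Nefm.

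The fixed gene lists had medians between -6.40 and 3.03 points, and several depended on the setting. With at least 10 calls per CpG, the medians of early lineage, Hox and feeder genes were -10.9, -5.07 and -7.63 points. The germline median was -1.42 points under that setting and 10.05 with mean CpG levels. With mean CpG levels, the medians of early lineage, Hox and feeder genes were -0.330, -2.25 and 0.441 points. Of 39 imprinted genes tested, 7 gained and 5 lost, with a list median of 2.72 points (percentile 92.8 among matched random lists). Magel2 and Mkrn3, of the Prader-Willi region, went from 9.84 to 34.9% and from 22.1 to 49.4%, and the long noncoding RNA genes H19 and Kcnq1ot1 from 62.7 to 83.7% and from 46.7 to 68.1%. H13, Zim1 and Cdkn1c also gained, while Snrpn (72.8 to 47.9%), Plagl1, Commd1, Rtl1 and Kcnq1 lost. Of 39 Hox genes, 0 gained and 4 lost: Hoxa3 (33.1 to 11%), Hoxd12 (32.7 to 10.6%), Hoxb3 and Hoxc4, with a median of -1.52 points (percentile 0.630). Early lineage genes were also low (median -1.53, percentile 1.73), with losses at Gata4, an endoderm and heart factor (79.0 to 52.8%), and Krt8, a keratin of simple epithelia, and a gain at Mesp1, among 30 tested. Clustered protocadherins, cell adhesion genes of neurons, had 3 gains among 58, at Pcdha1 (9.28 to 64.0%), Pcdha3 (11.4 to 34.1%) and Pcdha9 (17.7 to 39.8%), and 2 losses, at Pcdhb19 and Pcdhb21 (55.7 to 20.5%); the median was 3.03 points (percentile 93.1). Because 8 gamma genes share 1 window, the median over the 51 distinct windows was 0.703 points (percentile 62.2). Of 26 pluripotency genes, Sox2 gained (13.2 to 56.5%) on 1.49 times the wild-type coverage, and Esrrb lost (79.1 to 54%), with a median of 0.774 (percentile 66.7).

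Of 35 chromatin remodeller genes, 3 gained and 0 lost: Smarca5 itself, Chrac1, whose product partners SNF2H in the CHRAC complex (27.6 to 49.7%), and Atrx (18.9 to 45%), with a median of 1.55 (percentile 81.2). Of 17 DNA methylation genes, 1 gained, Mbd1, which encodes a methyl-CpG-binding protein (9.64 to 49.4%, and 5.88 against 69.2% in the add-backs), with a median of 2.33 (percentile 90.8). Of 37 germline genes, Syce1 of the synaptonemal complex (41.1 to 78.8%) and Tex19.1 (47.0 to 83.5%) gained and 0 lost (median 1.05, percentile 80.1). Of 14 genes of the 2-cell stage, 0 gained, and Pramel16 and Usp17la lost (median -6.40, percentile 49.5). Of 42 polycomb-bound developmental transcription factor genes, 0 gained and 0 lost (median 1.14, percentile 73.8), while 14 fibroblast feeder genes had gains at Fbn1 (29.4 to 55.8%) and Thy1 (11.9 to 36.4%) and 0 losses (median -1.13, percentile 64.1). The counts were the same when p was adjusted over the list alone. In the knockout library some highly transcribed genes combined high coverage with high levels (Rn7sk, the 7SK RNA gene, was 98.2% methylated at 41.7 times the mean coverage). Among gene ends where the knockout's coverage was less than 25% above that of wild type, 489 gained and 753 lost.

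**Figure D2:**
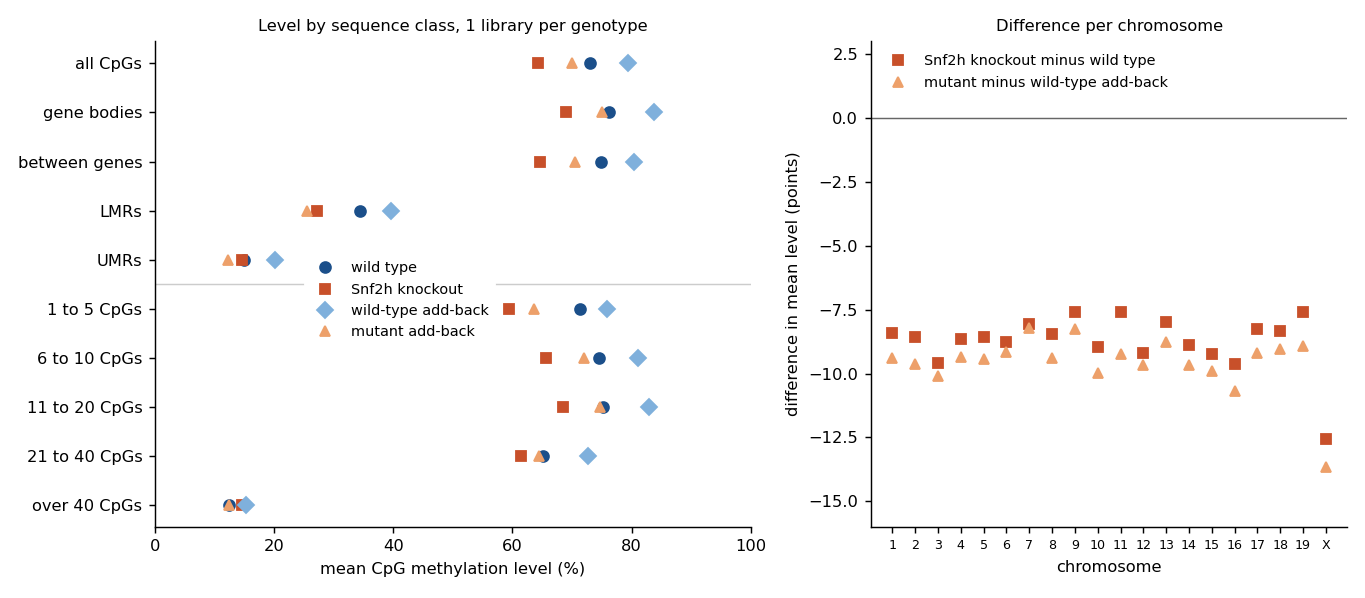
Left, mean CpG methylation level (%) by sequence class in each library; right, difference in mean level (points) per chromosome for knockout minus wild type and mutant minus wild-type add-back. Both differences are negative on 20 of 20 chromosomes, with autosomal means of -8.55 and -9.37 points and X at -12.6 and -13.7.

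The mutant add-back stood below the wild-type add-back, in the same knockout background, by a like amount. Yet the mutant add-back lay 5.57 points above the knockout, while the wild-type add-back lay 6.40 points above wild type. The mean level was 79.4% in the wild-type add-back and 69.9% in the mutant add-back, a difference of -9.49 points that was negative on 20 of 20 chromosomes (SD 0.597 over autosomes; X -13.7) and in 98.2% of the 100 kb windows. LMRs stood at 39.6 and 25.5% (difference -14.1 points, interval -14.4 to -13.8) and UMRs at 20.2 and 12.3% (difference -7.89, interval -8.34 to -7.45); under the stricter region definition these differences were -7.10 and -3.98. Gene bodies differed by -8.74 points and sequence between genes by -9.81. Depth allowed few tests of single regions: of 383 LMRs, 18 lost and 0 gained. These 383 are not typical LMRs. They stood at 20.6% in the wild-type add-back and differed by -8.13 points. The 52893 LMRs tested in knockout minus wild type stood at 34.3% and differed by -12.7 in the add-back pair. With at least 10 calls in place of 30, 93 of 11779 lost and 10 gained. With regions from wild type alone 44 of 1587 lost and 9 gained, and under the stricter definition 2 of 244 lost and 0 gained. Of 1522 tiles of 1 kb, 50 lost and 5 gained, and of 178875 windows of 10 kb, 10088 lost and 72 gained (5801 and 77 when centred on the median difference).

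At gene ends, 2 of 806 gained and 5 lost. Nefm rose from 18.8% (Wilson interval 8.89 to 35.3%, 32 calls) to 63.0% (48.6 to 75.5%, 46 calls; adjusted p = 0.0226, Fisher's exact test), and Nploc4, a ubiquitin-binding cofactor, from 7.14 to 46.7%. The losses were at Ikbkb, a kinase of NF-kappa-B signalling (43.3 to 6.25%), Prex2, a Rac exchange factor (62.9 to 18.4%), Brinp3 (83.3 to 40%), Catip (89.6 to 61.0%) and Tmem267 (91.4 to 67.9%). Of these 7 ends, only that of Nefm changed by 20 points or more in knockout minus wild type. Those of Brinp3 (-13.3 points, adjusted p = 0.0112) and Tmem267 (8.14 points, adjusted p = 0.0441) passed Fisher's exact test there below that size. Lists with members deep enough to test were imprinted (8 genes, median -17.0, percentile 9.68), germline (4, -3.67, percentile 62.5), early lineage (4, -3.50, percentile 27.5) and protocadherin genes (7, 15.0, percentile 98.6). None of their members changed when p was adjusted over all genes; adjusted over the list alone, 2 imprinted and 1 early lineage gene lost and 1 protocadherin gained.

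Taken as pooled sets, the LMRs and gene ends called in knockout minus wild type moved the same way in the add-back pair, which shares no library with it. Many single gained regions did not. The 7996 LMRs lost in the knockout stood at 48.7% in the wild-type add-back and 22.9% in the mutant (difference -25.8 points, interval -26.4 to -25.3), against -14.1 points (interval -14.8 to -13.4) at uncalled LMRs of like level. The 2257 gained LMRs stood at 24.2 and 34.6% (difference 10.3, interval 8.92 to 11.9), against -14.3 points (interval -16 to -12.8) at uncalled LMRs of like level. With at least 10 calls in both add-backs, 1423 of 1583 lost LMRs and 194 of 341 gained ones had the same sign. Of the 383 LMRs with at least 30 calls, 268 were lower and 108 higher in the mutant add-back, so a lower sign was the more common one. Gained gene ends differed by 4.54 points (interval 2.42 to 6.53) and lost ones by -16 (interval -17.8 to -14.3). Of 334 gained gene ends with at least 10 calls, 71 were higher in the mutant by 20 points or more and 36 lower, against 544 and 1639 of 10930 that were not called. By sign alone, 187 of the 334 were higher and 115 lower, against 3742 and 6037 of those not called. Of 378 lost ends, 75 were higher and 294 lower. Losses of 10 kb windows overlapped at 1141, where independent lists would share 329. Among the 377 LMRs tested in both pairs, 8 losses and 0 gains were shared, where independent lists would share 1.48 and 0. Among 805 gene ends, 0 losses and 1 gain were shared, where independent lists would share 0.0435 and 0.0398. Across 24938 windows of 100 kb the differences correlated (Pearson 0.592, Spearman 0.540). Windows are not independent replicates, and within single chromosomes Pearson's r ran from 0.310 to 0.714. Spearman's correlation was lower for smaller regions: 0.268 for 10 kb windows, 0.318 for LMRs, 0.219 for gene ends and 0.209 for 1 kb tiles.

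**Figure D3:**
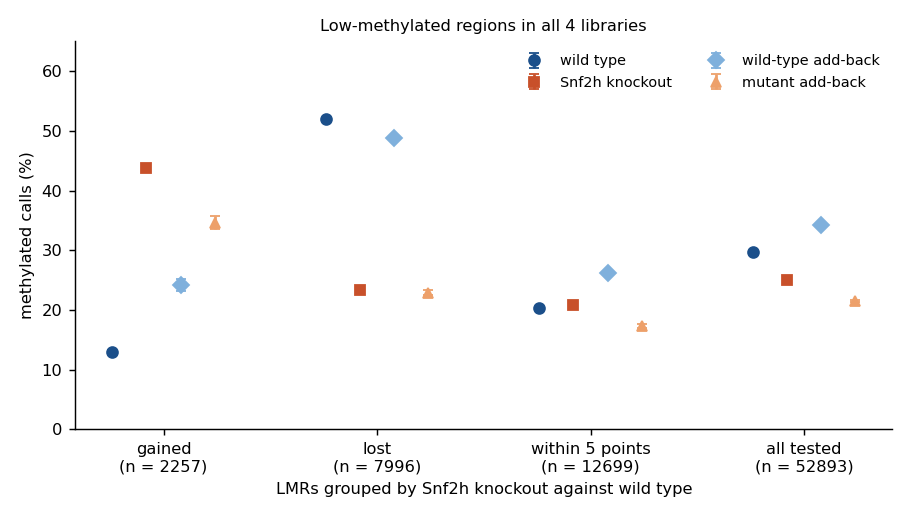
Methylated calls (%) in each library at LMRs gained, lost or within 5 points in knockout minus wild type, and at all tested LMRs, with 95% bootstrap intervals over regions. Lost LMRs stand at 52.0, 23.4, 48.7 and 22.9% in wild type, knockout, wild-type and mutant add-back, and gained LMRs at 12.9, 43.8, 24.2 and 34.6%.

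Adding wild-type SNF2H back to knockout cells went with higher methylation in every sequence class, and above the wild-type level. The wild-type add-back was 15.1 points above the knockout (SD 0.318 over autosomes) and 6.40 points above wild type (SD 0.444), higher on 20 of 20 chromosomes in both. LMRs were 12.5 points above the knockout (interval 12.2 to 12.7) and 5.24 above wild type (5.01 to 5.46), and UMRs 5.66 (5.28 to 6.06) and 5.33 (5.02 to 5.66). Under the stricter region definition LMRs were 4.33 and 5.64 points above, and UMRs 2.48 and 3.74. Against the knockout, 47676 of 193514 windows of 10 kb gained and 101 lost; against wild type, 3305 gained and 177 lost. Centred on the median difference, 1350 and 669 windows changed in either direction, and at equal depth 36452 of 179087 and 1411 of 178118. Of the LMRs, 72 of 979 gained and 17 lost against the knockout, and 13 of 982 gained and 4 lost against wild type. The 5.24 points at LMRs were -0.208 over CpGs with at least 5 calls in all libraries, and at equal depth 1 of 105 LMRs was called against wild type, where 17 of 982 had been.

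At gene ends, 74 of 1917 gained and 48 lost in the wild-type add-back against the knockout. Gains were led by Tmem156 (33.8 to 84.2%), Hnrnph1, a splicing factor (57.0 to 100%), Il17c (47.9 to 90.6%), 1810009A15Rik (1.95 to 41.9%) and Igfbp6 (23.3 to 62.8%). Losses were led by Ptma, prothymosin alpha (64.8% to 0 of 35 calls, Wilson interval up to 9.89%), the histone gene H2ac20 (59.5 to 3.12%), Igf2bp1, an mRNA-binding protein (55.1% to 0 of 62 calls, up to 5.83%), Dhx34 (69.5 to 18.8%) and Exosc6 of the RNA exosome (52.5 to 3.33%). The mutant add-back was low too at Ptma (16.7%), H2ac20 (9.09%), Igf2bp1 (0 of 19 calls) and Exosc6 (11.1%, 9 calls), but not at Dhx34 (75%). Wild type stood at 11.6, 3.54, 0.847, 16.5 and 11.5% in that order. At the ends other than Dhx34, only the knockout library was high. The knockout's coverage was 3.94 times that of wild type at H2ac20, but 0.727 times at Ptma, 0.845 at Igf2bp1 and 1.02 at Exosc6. List members that gained were Prdm14 (8.98 to 37.5%) and Nr5a2 (71.0 to 94.3%) of the pluripotency list, Hoxa3 (11 to 33.3%) and Otp (22.4 to 50%); Tex14 of the germline list lost (37.4 to 6.25%). Medians of the lists were 9.14 points for 10 imprinted, 0.888 for 5 germline, 20.3 for 4 pluripotency, 0.245 for 6 early lineage, 1.66 for 6 Hox, 4.98 for 3 polycomb-bound, 3.12 for 3 remodeller and -0.479 for 12 protocadherin genes tested. Their percentiles among matched random lists were 81.7, 29.3, 99.75, 79.5, 87.3, 98.4, 87.7 and 17.6 in that order.

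Against wild type, 44 of 1918 gene ends gained and 10 lost in the wild-type add-back. Gains were led by B3glct, a glucosyltransferase (19 to 70.8%), Zfp68 (11 to 56.7%), 1810009A15Rik (0.645 to 41.9%), Col25a1 (28.1 to 67.6%) and Fam171b (25.1 to 64.5%), and losses by Rmdn1 (58.3 to 16.3%), Errfi1 (61.4 to 20%), Vat1 (30.8% to 0 of 34 calls, Wilson interval up to 10.2%), Wdr38 (36.6 to 6.45%) and Rnaseh2c (43.2 to 13.9%). List members that gained were the imprinted gene Peg3 (36.2 to 64.6%), Prdm14 (5.16 to 37.5%) and Pcdha1 (9.28 to 37.5%). Medians were 9.15 points for 10 imprinted, 12.4 for 5 germline, 9.37 for 4 pluripotency, -0.295 for 6 early lineage, 0.781 for 6 Hox, 10.3 for 3 polycomb-bound, 6.33 for 3 remodeller and 7.14 for 12 protocadherin genes, at percentiles 69.2, 83.2, 94.5, 60.2, 63.4, 99.8, 94.6 and 68.6 in that order.

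The mutant add-back, knockout cells with the ATPase mutant, was also above the knockout, by 5.57 points (SD 0.376 over autosomes; higher on 20 of 20 chromosomes), but not at LMRs (-1.64 points, interval -1.85 to -1.42) or UMRs (-2.23, interval -2.53 to -1.92). Of 191998 windows of 10 kb, 2123 gained and 255 lost. Centred on the median difference, 887 changed in either direction, and at equal depth 313 of 179012. Of 1039 LMRs, 0 gained and 4 lost. Among 2186 gene ends 21 gained and 26 lost. Sox2 went from 56.5% in the knockout to 0 of 30 calls in the mutant add-back (Wilson interval up to 11.4%). At the same end, 0 of 20 calls were methylated in the wild-type add-back and 13.2% in wild type. Ptma (64.8 to 16.7%), Gjd2 (46.9 to 5.66%), Gdf10 (49.0 to 12.5%) and Zfp105 (37.8 to 3.33%) also lost. Gains were led by LOC100504180 (51.4 to 88.4%), Nop10 of the box H/ACA ribonucleoproteins (38.2 to 69.6%), Fcer1a (57.5 to 87.9%), Cfap52 (36.6 to 66.7%) and Ntrk2, the receptor of brain-derived neurotrophic factor (23.5 to 53.3%). List members that gained were the remodeller Chd7 (5.33 to 25.7%), Pcdha8 (55.5 to 82.6%) and Pcdhb22 (64.0 to 92.1%). Medians were 16.1 points for 9 protocadherin genes, -2.54 for 11 imprinted, 4.20 for 6 germline, -12.7 for 3 pluripotency, -1.71 for 6 early lineage, -5.10 for 8 polycomb-bound and -2.29 for 9 remodeller genes, and 0 for 9 Hox genes, at percentiles 99.86, 66.6, 81.9, 5.4, 80.3, 20.3, 56.8 and 83.1 in that order.

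Coverage was also compared between chromosomes within each library. At CpGs of like density, chromosome 1 had 1.47, 1.47, 1.45 and 1.43 times the autosomal median in wild type, knockout, wild-type and mutant add-back, and chromosome 14 had 1.35, 1.35, 1.33 and 1.38. The X chromosome lay between 0.443 and 0.507. Chromosome 8 had 0.983 in wild type and 0.985 in the knockout, against 1.04 in the wild-type and 1.13 in the mutant add-back.

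**Figure D4:**
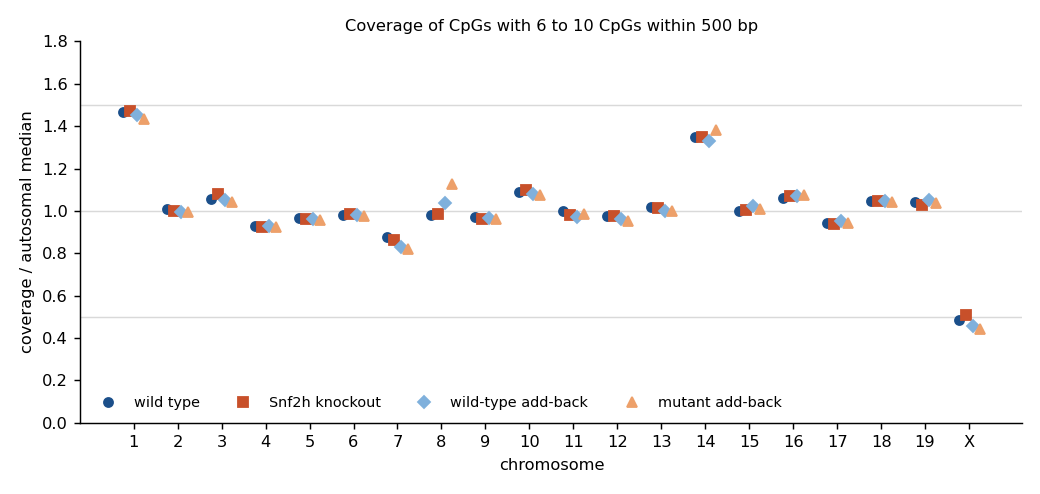
Coverage over the autosomal median (y axis) of CpGs with 6 to 10 CpGs within 500 bp, per chromosome and library. Chromosome 1 lies at 1.43 to 1.47 and chromosome 14 at 1.33 to 1.38 in all 4 libraries, and chromosome 8 reaches 1.13 in the mutant add-back.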

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

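Of the tests in this part, only that of gained LMRs more than 5 kb from any gene was set before its result was seen, at a time when the add-back difference of all gained LMRs was known; all others were chosen after the result was seen. Some replaced an earlier choice. The feeder test first used embryonic stem cell marker gene ends, which stood at 27.1% in the wild-type and 14.8% in the mutant add-back, but at 19.5% in wild type and 28.9% in the knockout, so the pairs went opposite ways. The cell line test first used splits of the libraries into pairs. The gene end test first used histone genes, and the test of copies first asked for exon positions, which were not used here. Uncalled LMRs were first taken within 5 points and then matched on level.

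Methylation was lower in both libraries without working SNF2H, by -8.67 and -9.49 points. Less complete conversion in the libraries with SNF2H would raise their mitochondrial DNA too, but outside the rRNA genes wild type minus knockout was -1.29 points. DNA from fibroblast feeders would dilute the excess coverage of chromosomes 1 and 14, if that excess belongs to the stem cells and is equal in both lines. The upper bootstrap limits of the foreign share, over windows, were 1.16% in the knockout and 1.33% in the mutant add-back. Fully unmethylated DNA would need 11.9 and 12.0%. From wild-type to mutant add-back, chromosome 1 fell from 1.45 to 1.43 times the autosomal median, but chromosome 14 rose from 1.33 to 1.38. Dilution alone would not give that rise, so the limit in the add-back pair is less sure. Differences between derived cell lines unrelated to SNF2H stay open, since both lines with SNF2H differed by 6.40 points from each other and genotype, clone and past feeder culture cannot be told apart with 1 library per genotype. Loss of SNF2H activity, which the design names, may underlie the shared direction and stays untested against these.

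Against this wider loss, 2257 LMRs and 587 gene ends gained methylation in the knockout over wild type. Sampling noise would leave the gained LMRs like uncalled ones in the add-back pair, but they differed by 10.3 points there and uncalled LMRs of like level by -14.3, which leaves room for noise at single LMRs. Unconverted reads of transcript origin would spare regions far from genes, but the 526 gained LMRs more than 5 kb from any gene differed by 11.9 points (interval 9.01 to 14.8) in the add-back pair. At gene ends such reads would need 1.74 times the coverage, and the gained ends had 1.05 times (interval 0.992 to 1.10), although 52 ends reached the ratio and the 58 replication-dependent histone genes, which first pointed to such reads, stood at 79.5% in the knockout, 33.9% in wild type and at most 5.08% in the add-backs. Differences between lines stay open, since 241 LMRs were at least 10 points higher in both libraries without working SNF2H, and the other splits gave 267 and 234. Single ends such as Sox2, gained in the knockout alone, stay open too, and a role of SNF2H, which the design names, was not tested against these.

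In the mutant add-back, 15 CpGs inside Smarca5 had 194 times the library's mean coverage, a signal outside the methylation comparisons. Unconverted reads of transcript origin would be near fully methylated, as the 98.2% at Rn7sk in the knockout, but 72.9% of these calls were. A gain of the whole locus would raise the gene's other CpGs alike, which had 1.81 times the mean. Integrated copies of a Smarca5 cDNA would give separate runs of excess, as the introns would be missing, and the 15 CpGs fell into 8 runs with 92 other CpGs between them, so an added-back cDNA is a candidate explanation. The wild-type add-back, at 2.89 times the mean on the same CpGs, showed no such excess, and no value here says why.

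UMRs differed between the pairs: knockout minus wild type exceeded mutant minus wild-type add-back by 7.56 points (bootstrap interval 7.11 to 8.01). CpGs with over 40 CpGs within 500 bp differed by 2.18 points in knockout minus wild type and by -2.84 in the add-back pair, opposite directions whose difference was not tested. Mitochondrial rRNA genes, outside the chromosomes compared, were 18.0% methylated in the knockout, 4.28% in wild type, and 1.23 and 1.22% in the add-backs. Chromosome 8 had 1.147 times the wild-type coverage in the mutant add-back, also a signal outside the methylation comparisons.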

How the results depend on the processing

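Each setting was fixed before the data were examined, apart from the gene end window, the 10-call minimum in the naming rule and the settings that follow. Chosen after seeing the data were the minimum of 1 call per CpG for mean levels, region tests without a minimum per CpG, the coverage limit and its absence. So were at least 10 calls per region, the CpG-poorer gene end, the limit on knockout coverage and distance from genes. Regions from wild type and knockout only and each window counted once were also chosen then. The same holds for all settings of the 10 kb windows, and of the add-back difference at LMRs called in the knockout. Of the 263 alternative values, 111 kept their direction and size or side of the threshold, 68 were lower counts, 16 higher counts, 60 moved without a change of sign and 8 changed sign. Among these 8 were the list medians of germline genes in knockout minus wild type (-1.42 with at least 10 calls per CpG) and in the add-back pair (1.42 with mean CpG levels), and that of feeder genes in knockout minus wild type (0.441 with mean CpG levels). Genome-wide differences kept their sign under every setting run, from -10.9 to -8.58 points in knockout minus wild type, -10.7 to -9.40 in the add-back pair, 12.2 to 16.8 in wild-type add-back minus knockout, 2.37 to 6.44 in wild-type add-back minus wild type and 1.62 to 6.11 in mutant add-back minus knockout. The 12.2, 2.37 and 1.62 rest on only the 309 CpGs with at least 10 calls in all libraries. The add-back difference at LMRs gained in the knockout ran from 9.66 to 18.7 points, and at lost LMRs from -28.7 to -24.5. No paired analysis was possible because the labels give no replicate numbers and each genotype has 1 library. The pairs with and without working SNF2H hold different genotypes, so they were compared side by side and not fitted as replicates. No library could be left out in turn. Alternatives for the CTCF, REST, OCT4-SOX2, NRF1 and YY1 motifs were not run. Coverage minimums gave no value for region tests with under 100 regions, mean levels with under 100 CpGs and lists with too few genes. Stricter settings test or call fewer regions by construction; the cause of the other shifts was not tested. Regions from the wild-type add-back alone, the library outside knockout minus wild type, were 517 LMRs and 1 UMR, so values from them say little. Depth limits which regions could be tested: 52893 LMRs had enough calls in knockout minus wild type and 383 in the add-back pair. Among the regions tested, 10.4, 46.3 and 68.2% of simulated shifts of 20, 30 and 40 points were recovered in the first and 23.4, 76.6 and 92.1% in the second. These rates cannot be compared between the pairs, since the shifted regions made up a far larger share of the 383 LMRs than of the 52893. The adjusted p depends on that share. Far fewer of the 52893 LMRs were shifted than were called in the data, so the first rates do not describe recovery of the real changes. A simulated shift of 20 points also equals the required difference, so many such shifts fall below it by sampling. Only gains were simulated, with independent calls, so the rates do not cover losses or calls that share a read.

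Letters stand for knockout minus wild type (A), mutant minus wild-type add-back (B), wild-type add-back minus knockout (C), wild-type add-back minus wild type (D) and mutant add-back minus knockout (E); differences are in points. With at least 5 calls per CpG, the genome-wide difference was -10.5 in A, -10.3 in B, 4.48 in D and 4.68 in E. The LMR difference was -12.1 in A, -14.8 in B, 11.9 in C, -0.208 in D and -2.87 in E. The UMR difference was 1.44 in A, 3.82 in C and -4.05 in E. LMRs numbered 1054 gained in A and 6034 lost in A. Gene ends numbered 204 gained in A and 627 lost in A. 1 kb tiles numbered 2589 gained in A and 70761 lost in A. With at least 10 calls per CpG, the difference over the 309 CpGs left was 12.2 in C, 2.37 in D and 1.62 in E. LMRs numbered 441 gained in A and 4065 lost in A. Gene ends numbered 111 gained in A and 313 lost in A. 1 kb tiles numbered 1256 gained in A and 39842 lost in A. List medians in A were 4.48 for imprinted genes, -1.42 for germline genes, 2.60 for pluripotency genes, -10.9 for early lineage genes, -5.07 for Hox genes, 2.82 for polycomb-bound genes, 4.56 for remodeller genes and -7.63 for feeder genes. With summed calls in place of mean CpG levels, the genome-wide difference was -9.62 in A, -9.57 in B, 15.6 in C, 5.996 in D and 6.04 in E. The LMR difference was -9.37 in A, 11.9 in C, 2.5 in D and -2.39 in E. The UMR difference was -0.0271 in A, 4.03 in C, 4.00 in D and -3.98 in E. On autosomes only, the genome-wide difference was -8.58 in A, -9.40 in B, 15.0 in C, 6.44 in D and 5.62 in E. With summed calls and no coverage limit, the genome-wide difference was -10.9 in A, -10.7 in B, 16.8 in C, 5.96 in D and 6.11 in E. With regions of at least 6 CpGs under a level of 30%, the LMR difference was 1.31 in A, -7.10 in B, 4.33 in C, 5.64 in D and -2.77 in E. The UMR difference was 1.26 in A, -3.98 in B, 2.48 in C, 3.74 in D and -1.50 in E. LMRs numbered 531 gained in A, 293 lost in A, 0 gained in B, 2 lost in B, 18 changed in C and 7 changed in E. With regions from 1 library outside the comparison, the LMR difference was -10.4 in A and -7.72 in B. The UMR difference was 7.40 in A and -6.03 in B. LMRs numbered 4 gained in A, 33 lost in A, 9 gained in B and 44 lost in B. With a required difference of 30 points, LMRs numbered 1140 gained in A, 3629 lost in A, 48 changed in C, 10 changed in D and 2 changed in E. Gene ends numbered 194 gained in A, 208 lost in A, 2 gained in B, 3 lost in B, 43 changed in C, 25 changed in D and 16 changed in E. 1 kb tiles numbered 2686 gained in A and 44933 lost in A. 10 kb windows numbered 10 gained in A, 436 lost in A, 26 gained in B, 5164 lost in B, 4924 changed in C, 214 changed in D and 202 changed in E. LMRs gained in A differed by 18.7 points in B. LMRs lost in A differed by -28.7 points in B. With differences centred on their median and Fisher's exact test left uncentred, LMRs numbered 2996 gained in A and 5129 lost in A. 1 kb tiles numbered 7610 gained in A and 55878 lost in A. 10 kb windows numbered 331 gained in A, 690 lost in A, 77 gained in B, 5801 lost in B, 1350 changed in C, 669 changed in D and 887 changed in E. With at least 10 calls per region, LMRs numbered 10 gained in B, 93 lost in B, 1032 changed in C, 123 changed in D and 34 changed in E. Gene ends numbered 11 gained in B, 32 lost in B, 447 changed in C, 190 changed in D and 125 changed in E. With all libraries thinned to the depth of the shallowest, LMRs numbered 2 changed in C, 1 changed in D and 0 changed in E. Gene ends numbered 10 gained in A, 0 lost in A, 17 changed in C, 4 changed in D and 4 changed in E. 1 kb tiles numbered 4 gained in A and 3 lost in A. 10 kb windows numbered 24 gained in A, 1668 lost in A, 1411 changed in D and 313 changed in E. At the CpG-poorer gene end, gene ends numbered 181 gained in A, 1145 lost in A, 0 gained in B, 11 lost in B, 24 changed in D and 13 changed in E. With 500 bp on each side of the gene end, gene ends numbered 692 gained in A, 565 lost in A, 20 changed in C, 16 changed in D and 4 changed in E. With mean CpG levels in place of summed calls, gene ends numbered 1 gained in B, 5 lost in B and 30 changed in E. List medians in A were 10.05 for germline genes. At gene ends with knockout coverage less than 25% above wild type, gene ends numbered 2 gained in B and 2 lost in B. With no coverage limit, 1 kb tiles numbered 6 gained in B and 90 lost in B. With each window counted once, list medians in A were 0.703 for protocadherin genes. More than 5 kb from any gene, LMRs gained in A differed by 11.9 points in B. LMRs lost in A differed by -24.5 points in B.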

Other observations

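The groupings of genes and windows in this part were chosen after the data were seen and were not tested. The clustered protocadherins, which give neurons their surface identity, did not move as 1 group. Ends of the 14 alpha genes stood at 24.7% in wild type (Wilson interval 23.3 to 26.1%) and 35.2% in the knockout (33.6 to 36.8%), and at 32.7% in the wild-type add-back (28.3 to 37.5%) and 49.7% in the mutant (44.3 to 55.1%). Of 12 alpha ends with at least 10 calls in each library, 9 were higher in the knockout than in wild type and 11 higher in the mutant than in the wild-type add-back. Ends of the 22 beta genes stood at 48.5, 44.3, 49.9 and 49.6% in the same order. Ends of the 22 gamma genes, 8 of which share 1 window, stood at 24.4, 26.4, 37.9 and 31.3%. Of 12 distinct gamma windows with as many calls, 6 were higher in the knockout and 3 in the mutant add-back.

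On autosomes the size of the difference followed gene content in knockout minus wild type but not in order in the add-back pair. In 8288 autosomal windows of 100 kb without a gene, knockout minus wild type was -11.3 points and mutant minus wild-type add-back -10.8. In 11709 windows with 1 or 2 genes the values were -7.85 and -8.90, and in 3550 windows with 3 or more genes -6.03 and -9.23. Split by the presence of working SNF2H, 23310 of 178875 windows of 10 kb had both libraries without it at least 10 points below both others, and 23 had them above. The split of add-backs from the other lines gave 5596 with the add-backs higher and 130 lower, and the remaining split 43 and 331. Among 11765 LMRs the split by SNF2H gave 2127 below and 241 above, but the other splits gave as many or nearly as many above, 267 with the add-backs higher and 234 in the remaining split, with 251 and 109 below. Among 806 gene ends the SNF2H split gave 16 below and 14 above, that of the add-backs 12 lower and 15 higher, and the remaining split 0 and 5. Among 298 UMRs more than 5 kb from any gene, knockout minus wild type was -2.22 points (bootstrap interval -4.56 to 0.0361) and mutant minus wild-type add-back -16.8 (-19.2 to -14.6). The 7SK RNA gene Rn7sk had 7.29 times the mean coverage in wild type, with 92.4% of calls methylated, and 2 calls in each add-back library, 0 of them methylated.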
